A study of Mus musculus with 8 samples.

How the data were processed

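The study measured RNA and chromatin accessibility together in single nuclei (10x Genomics Chromium Multiome ATAC + Gene Expression) of sorted CD4+ T cells with high CD44 from the lung-draining lymph nodes of papain-treated mice. Cells were lysed for 3 minutes to free the nuclei, per the labels' protocols. The 8 samples were the RNA and the ATAC part of 4 libraries, 2 Ctrl (floxed Zfp148 and Zfp281, no Cd2-Cre) and 2 pdKO (the same alleles with Cd2-Cre). The pdKO cells were sorted for YFP in addition, so the sort gate and the genotype differ together.

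The authors ran Cell Ranger ARC 2.0.1 with the mm10 build of the mouse genome, per the submitters' processing notes and the version and genome fields inside the deposited summaries. The gene annotation was not given in the sources used here. For each library a table of all barcodes and a summary of 1 line were used. The barcode tables hold raw counts per barcode as deposited by the authors: reads, UMIs (unique RNA molecules), genes, unique ATAC fragments, fragments at TSS and in peaks, and mitochondrial reads, none of them normalised. They also hold the pipeline's call of each barcode as a cell, and a code for excluded barcodes whose values are not explained in the tables and which was not used for any filter. The deposited summaries give numbers of cells, peaks and linkages as counts, shares of reads as a fraction from 0 to 1, a TSS enrichment score per library, and coverage per cell as mean reads or median fragments, signal values not corrected for depth. Peaks, cells and linkages were called per library by the authors' pipeline, per the file headers. The barcode tables and the summaries agreed: recomputed numbers of cells and medians of UMIs, genes and fragments differed from the summary values by 0 in all 4 libraries, and exonic plus intronic UMIs equalled the UMI count in every line.

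The tables of the series were assigned to samples by the genotype and replicate in the name the authors gave each table, which matches 1 title per measurement. For replicate 1 an identifier inside the summaries names the genotype too. For replicate 2 it does not, so that the genotype of these 2 libraries rests on the name of the table alone. No value per gene was used here, so the state of Zfp148 and Zfp281 transcripts was not checked against the labels, no gene is named as a result and nuclei were not assigned to cell types. The rule for named genes, fixed before the data were examined, puts the 15 library measures in their place and reports all of them.

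Nuclei were the barcodes that the authors' pipeline called as cells, and no further filter or doublet caller was applied. For every nucleus the intronic share was intronic UMIs over exonic plus intronic UMIs, the TSS and peak shares were those fragments over all unique fragments, and the mitochondrial share was mitochondrial over raw ATAC reads, each in percent. The library value was the median over nuclei. Spread was the ratio of the 90th to the 10th percentile, the upper tail was the percent of nuclei above 3 times the library's median UMIs, and the relation of RNA to chromatin was Spearman's rho across the nuclei of a library. UMIs per nucleus could not be thinned to 1 depth without a gene matrix, so genes were compared within UMI bins 0.1 wide on the log10 scale that held at least 20 nuclei in each library. These 14 bins took in at least 97.0% of each library's nuclei. Counts, medians of counts and spreads were compared on the log2 scale, shares in percentage points.

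Each measure gave 1 value per library. The difference in means, pdKO minus Ctrl, was tested with the exact two-sided permutation test over the 6 assignments of 4 libraries to 2 groups, and the call was whether the ranges were separate. The difference within each replicate number was computed beside it, since the replicates differed in sequencing depth. Intervals of medians are 95% order-statistic intervals and those of shares 95% Wilson intervals, and both cover the sampling of nuclei in a library only. The tests, the saturation model and the matched bins were tested on simulated data: a shift of 0.5 in log2 UMIs planted in a split of Ctrl replicate 1 (8015 nuclei) was recovered as 0.508, a shift of 5 percentage points in the intronic share as 5.29, and a shift of 0.2 in log2 genes at matched UMIs as 0.201.

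The libraries held 402466532, 321193737, 451495202 and 351554023 RNA read pairs and 97414033, 383496234, 110993121 and 389054804 ATAC read pairs (Ctrl 1, Ctrl 2, pdKO 1, pdKO 2). Of the RNA reads 85.6, 74.1, 84.2 and 75.6% were duplicates, and of the ATAC read pairs 28.4, 40.4, 29.0 and 39.9%, per the deposited summaries. Alternatives fixed in advance were nuclei with at least 1000 UMIs and 1000 fragments, nuclei without the top 5% by UMIs or fragments, mean log2 values or pooled shares in place of medians, equal reads per nucleus from a saturation model of unique molecules against reads, bins 0.2 wide, a tail limit of 2 times the median, the 75th to 25th percentile ratio, Pearson's r, a replicate block with its exact sign-flip test, and leaving out each library. Alternatives without intergenic-rich nuclei (an intergenic share of RNA reads above 2 times the library's median) and, for matched UMIs, with bins of at least 100 nuclei, bins weighted by their nuclei and bins 0.05 wide were chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.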

Results

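Nuclei of activated CD4+ T cells were profiled for RNA and for open chromatin at the same time, in mice whose genes for the zinc finger transcription factors Zfp148 and Zfp281 were left intact or targeted by Cre in lymphocytes. The mice had been given papain, a plant protease that provokes type 2 inflammation in the airways. They received 40 µg per day through the nose in 2 periods of 3 days with a rest of 10 days between them, and their lung-draining lymph nodes were taken on day 16. CD4+ cells with high CD44, a surface marker of T cells that have met antigen, were sorted from these nodes. Control nuclei (Ctrl) came from mice that carried floxed alleles of both genes without the Cd2-Cre transgene. The mutant nuclei (pdKO, as the labels name them) came from mice that also carried Cd2-Cre, and were sorted in addition for YFP from the Rosa26 locus, a reporter that was not part of the Ctrl gate. Each genotype had 2 replicates, and every replicate gave an RNA and an ATAC measurement of the same nuclei, so that the 8 samples formed 4 libraries.

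The 4 libraries held 41090 called nuclei among 2872495 barcodes. Ctrl replicates 1 and 2 gave 8015 and 11546 nuclei, and pdKO replicates 1 and 2 gave 7953 and 13576. RNA sequencing was deeper in replicate 1, with 50214 reads per nucleus in Ctrl and 56770 in pdKO against 27819 and 25895 in replicate 2. ATAC sequencing was deeper in replicate 2, with 33215 read pairs per nucleus in Ctrl and 28658 in pdKO against 12154 and 13956 in replicate 1. Summed over nuclei, the libraries held 28551907, 45977174, 32577616 and 43230347 UMIs (unique molecules of RNA) and 56112373, 193064180, 63599190 and 201501600 unique ATAC fragments, in the order Ctrl 1, Ctrl 2, pdKO 1 and pdKO 2. The replicate number went with depth, so differences within each replicate number stand beside the pooled ones. The library was the unit of replication, and nuclei were not counted as replicates. With 2 libraries against 2 the exact two-sided permutation test cannot give a p below 0.333, and a comparison is described by whether the ranges of the library values were separate, which chance alone gives in 33.3% of comparisons. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

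The number of nuclei recovered did not differ between the genotypes beyond the spread of the replicates. The mean was 9781 ± 2497 in Ctrl and 10765 ± 3976 in pdKO (SD, n = 2 libraries each), a fold of 1.08 on the log2 scale (exact permutation p = 1). Within replicates the folds of pdKO over Ctrl were 0.992 and 1.18. Loading and the extra YFP gate of pdKO enter this number as well as the genotype.

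The RNA content of activated CD4+ T cell nuclei differed between the genotypes in opposite directions in the replicates, so no common difference was seen. The median nucleus held 3043 UMIs in Ctrl replicate 1 (95% order-statistic interval 3010 to 3074) and 3251 in Ctrl replicate 2 (3223 to 3282). In pdKO it held 3460 UMIs in replicate 1 (3425 to 3489) and 2570 in replicate 2 (2552 to 2588). The pdKO to Ctrl fold was therefore 1.14 in replicate 1 and 0.791 in replicate 2, and the pooled fold was 0.948 (exact permutation p = 1). Genes detected per nucleus followed the same pattern, with medians of 1604 and 1669 in Ctrl and 1736 and 1406 in pdKO and a pooled fold of 0.955 (exact permutation p = 1). The intervals cover the sampling of nuclei within a library only, and the distance between the pdKO replicates was many times wider than they are.

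**Figure D1:**
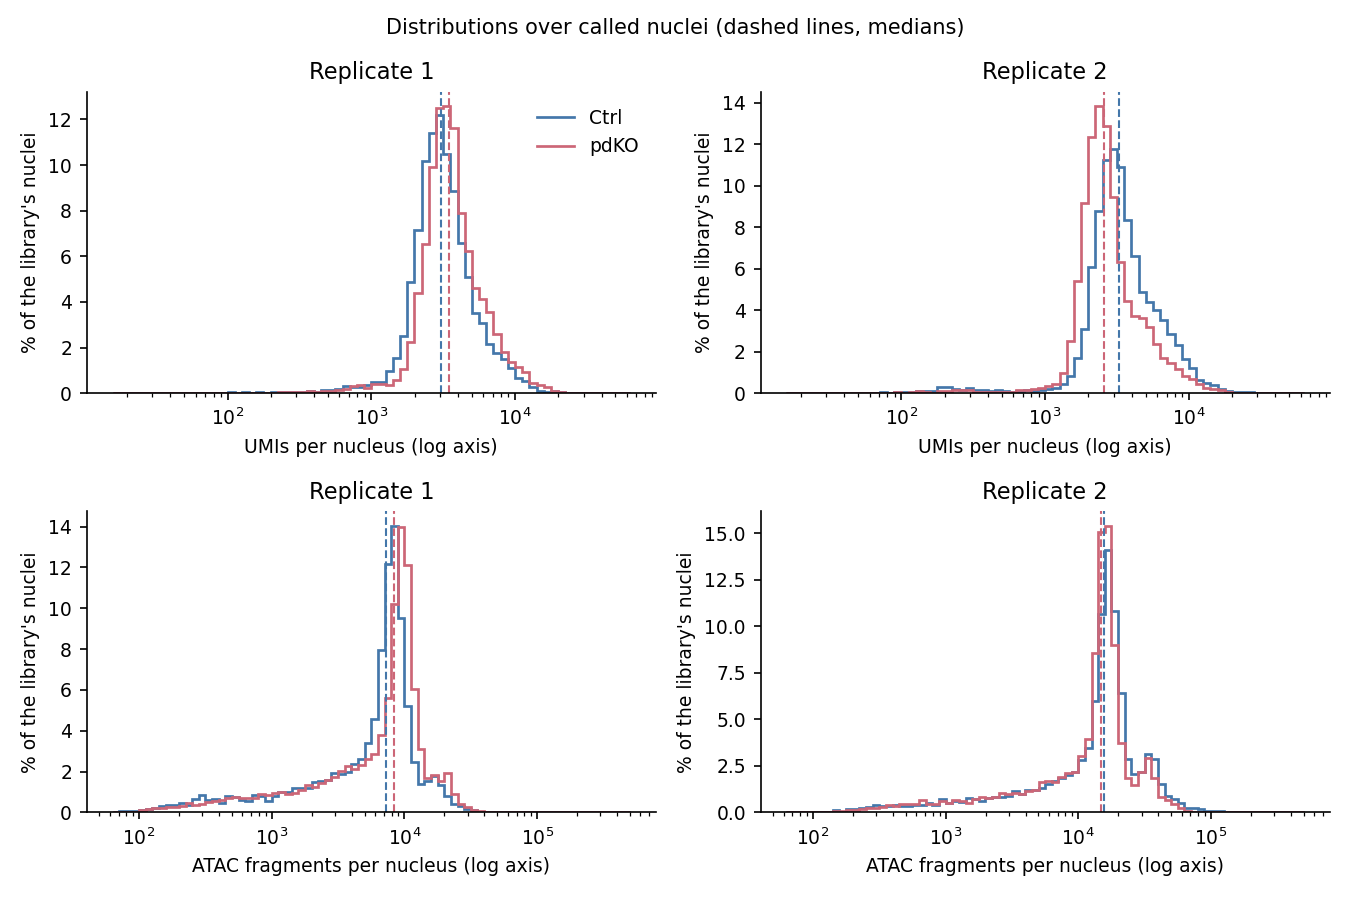
Distribution of UMIs (top) and unique ATAC fragments (bottom) per nucleus on log axes, with the percent of each library's nuclei on the vertical axis, Ctrl in blue, pdKO in red and dashed lines at the medians. For UMIs the pdKO curve lies to the right of Ctrl in replicate 1 (medians 3460 and 3043) and to the left in replicate 2 (2570 and 3251), while the ATAC curves of the genotypes lie close together and differ more between the replicates.

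Within bins of similar RNA content, slightly fewer genes were detected in pdKO nuclei on average, though not in every bin. In 14 bins of UMIs from 631 to 15849, each filled by at least 20 nuclei of every library, the geometric mean over bins of the median gene counts was 1580 and 1584 genes in Ctrl and 1565 and 1552 in pdKO. The ranges were separate and the difference was −0.02 on the log2 scale, a fold of 0.985 (exact permutation p = 0.333, the smallest possible). The folds were 0.991 in replicate 1 and 0.980 in replicate 2. In replicate 1 pdKO was below Ctrl in 10 bins and above it in 4, which held 49.3% of the Ctrl and 37.5% of the pdKO nuclei, and in replicate 2 it was below in 13 bins and above in 1. The direction and the separation held under each alternative with all 4 libraries, but the log2 difference was only −0.01 among nuclei with at least 1000 UMIs and 1000 fragments, over the 8 bins that held at least 100 nuclei of every library, with bins weighted by their nuclei and with narrower bins.

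Intronic UMIs made up a smaller part of all UMIs in pdKO, by a small amount in replicate 1 and by a larger one in replicate 2, where the Ctrl library stood above the other 3 libraries. Whether these UMIs came from unspliced transcripts or in part from copied genomic DNA was not measured. They were 41.9% of the UMIs of the median nucleus in Ctrl replicate 1 and 46.3% in Ctrl replicate 2, against 41.3% and 40.1% in pdKO. The group means were 44.1% ± 3.10 in Ctrl and 40.7% ± 0.879 in pdKO (SD, n = 2 each), and the ranges were separate (difference −3.41 percentage points, exact permutation p = 0.333). The difference was −0.592 points in replicate 1 and −6.22 points in replicate 2. Without Ctrl replicate 2 it shrank to −1.21 points, and without Ctrl replicate 1 it grew to −5.60. Without the nuclei rich in intergenic reads, an alternative chosen after seeing the data, the ranges were no longer separate (−3.02 points) and replicate 1 went the other way, with 42.3% in Ctrl and 42.6% in pdKO, so that the difference then rested on replicate 2 (46.5% and 40.2%).

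The intronic share depended on how much RNA a nucleus held, and in bins with at least 100 nuclei of every library this relation was similar in both genotypes of replicate 1. In nuclei with 2512 to 3162 UMIs it was 43.6% in Ctrl and 43.6% in pdKO of replicate 1, and 47.7% and 41.7% in replicate 2. In RNA-rich nuclei with 7943 to 10000 UMIs it was lower in every library, at 32.3% and 32.1% in replicate 1 and 42.3% in Ctrl and 28.1% in pdKO of replicate 2. RNA-poor nuclei with 794 to 1000 UMIs were lower too, at 35.7% in Ctrl and 30.9% in pdKO of replicate 1 and 38.4% and 22.5% in replicate 2. In most bins with fewer nuclei pdKO of replicate 1 lay below Ctrl, as at 10000 to 12589 UMIs (27.9% against 31.4%). Averaged over the 8 bins that held at least 100 nuclei of every library, the share was 39.8% and 45.6% in Ctrl and 39.7% and 37.6% in pdKO. The nuclei of Ctrl replicate 2 thus kept a higher intronic share at each of these RNA contents.

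**Figure D2:**
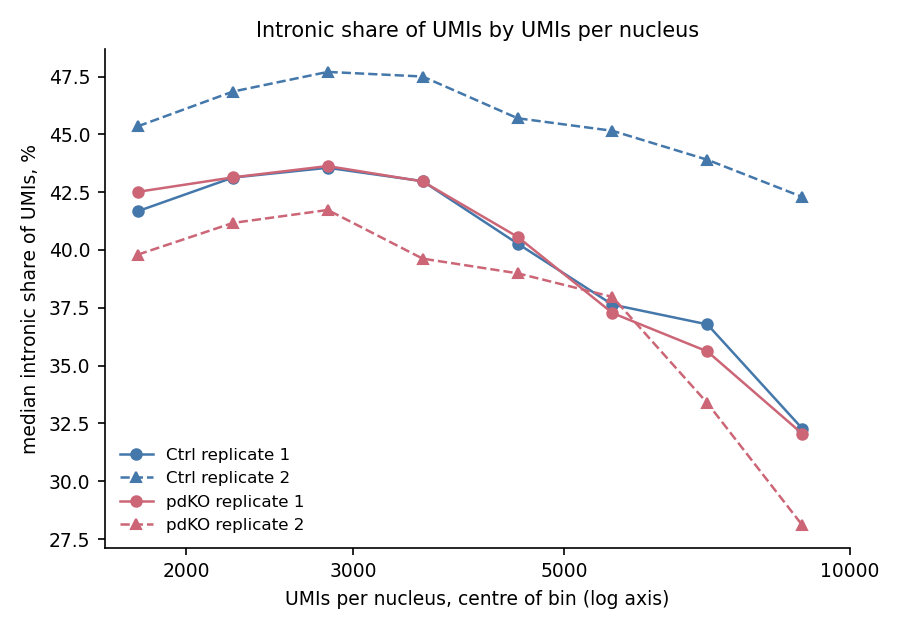
Median intronic share of UMIs (percent) against UMIs per nucleus (log axis), in 8 bins with at least 100 nuclei in every library. Points are library medians, with Ctrl in blue, pdKO in red, circles and solid lines for replicate 1 and triangles and dashed lines for replicate 2. The curves of replicate 1 overlie each other while Ctrl replicate 2 lies above the other 3 libraries in every bin, and the vertical axis does not start at 0.

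The spread of RNA content between nuclei was somewhat lower in pdKO within both replicates, but its ranges overlapped. The ratio of the 90th to the 10th percentile of UMIs was 3.17 and 3.50 in Ctrl and 3.13 and 3.18 in pdKO, a fold of 0.947 with overlapping ranges (exact permutation p = 0.667). Nuclei with more than 3 times their own library's median UMIs, a tail that can hold large or dividing cells as well as doublets, made up 2.68% of Ctrl replicate 1 (215 nuclei, 95% Wilson interval 2.35 to 3.06%) and 3.47% of Ctrl replicate 2 (401 nuclei, 3.15 to 3.82%). In pdKO they were 2.98% of replicate 1 (237 nuclei, 2.63 to 3.38%) and 4.12% of replicate 2 (559 nuclei, 3.80 to 4.46%). The share was higher in pdKO by 0.298 and 0.644 percentage points within the replicates, but the ranges overlapped (exact permutation p = 0.667), and with a limit of 2 times the median the pooled difference turned from 0.471 to −0.176 points. Without intergenic-rich nuclei replicate 1 went the other way, with 2.69% in Ctrl and 2.56% in pdKO.

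A smaller part of the RNA reads of pdKO fell on annotated transcripts. The summary of each library gave 65.7% and 65.4% of reads mapped confidently to the transcriptome in Ctrl and 61.1% and 60.8% in pdKO. The difference was −4.62 percentage points in replicate 1 and −4.63 points in replicate 2, with separate ranges (exact permutation p = 0.333). Reads in antisense orientation to a gene were 15.2% and 14.3% in Ctrl and 15.6% and 18.5% in pdKO, and reads in intergenic regions were 11.2% and 13.2% in Ctrl and 15.6% and 13.4% in pdKO. The near-equal differences thus came with unlike shifts. In replicate 1 the gap between the genotypes lay mainly in intergenic reads, and in replicate 2 mainly in antisense reads. Replicate 1 held a set of intergenic-rich nuclei, 11.9% of Ctrl and 28.7% of pdKO, with median intergenic shares of 26.5% and 28.8%. In its other nuclei the median share was 6.61% in Ctrl and 7.15% in pdKO. The summaries give no value without this set, so its part in the gap was not measured. The comparison of reads on the transcriptome was chosen after the values had been seen. It is not among the 15 measures fixed before the data were examined.

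Fragment yield, promoter share and peak share of open chromatin had overlapping ranges in the genotypes, with opposite directions in the replicates. The median nucleus held 7201 and 15735 unique ATAC fragments in Ctrl and 8412 and 14887 in pdKO (fold 1.05, exact permutation p = 1), and the folds within replicates were 1.17 and 0.946. At equal read pairs per nucleus, estimated from a saturation model, the medians were 7201 and 7875 in Ctrl and 7683 and 8244 in pdKO. The folds were then 1.07 and 1.05, so that the direction in replicate 2 turned and pdKO was higher within both replicates, with overlapping ranges (exact permutation p = 0.667). Fragments at transcription start sites (TSS), the promoters of genes, were 56.0% and 51.3% in Ctrl and 54.2% and 52.2% in pdKO. Their means were 53.7% ± 3.34 and 53.2% ± 1.38 (SD, n = 2 each, exact permutation p = 1), with differences of −1.83 and 0.937 percentage points within replicates. Fragments in called peaks were 72.9% and 67.4% in Ctrl and 71.4% and 68.2% in pdKO, with differences of −1.49 and 0.832 points within replicates (exact permutation p = 1). The deposited TSS enrichment scores were 17.7 and 15.4 in Ctrl and 17.0 and 15.7 in pdKO.

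The number of genes linked to accessible regions followed the replicate more than the genotype, and the number of these regions (peaks) had overlapping ranges. Between 91292 and 101352 peaks were called per library, with 91292 and 101352 in Ctrl and 93018 and 97084 in pdKO (fold 0.988, exact permutation p = 1), and peaks covered 2.88, 3.15, 2.93 and 3.02% of the genome in the order Ctrl 1, Ctrl 2, pdKO 1 and pdKO 2. Genes linked to at least 1 peak by covariation across nuclei numbered 3569 and 6738 in Ctrl and 3402 and 6641 in pdKO, a pooled fold of 0.969 (exact permutation p = 0.667). Linked genes were 0.953-fold and 0.986-fold as many in pdKO within replicates, while replicate 2 held 1.89 times the linked genes of replicate 1 in Ctrl and 1.95 times in pdKO. Peak to gene linkages numbered 13029 and 77045 in Ctrl and 12396 and 126450 in pdKO, with overlapping ranges. Within replicates pdKO held 0.951 and 1.64 times the linkages of Ctrl, so that the genotypes lay apart in replicate 2, and the cause was not tested.

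Mitochondrial reads in the ATAC libraries, which come from mitochondria left on the nuclei, differed strongly between the replicates and little between the genotypes. They were 3.64% of the ATAC reads of the median nucleus in Ctrl replicate 1 and 3.07% in pdKO replicate 1, and 0.509% and 0.709% in replicate 2. The difference between genotypes was −0.188 percentage points (exact permutation p = 1), with −0.576 and 0.2003 points within replicates. Without the nuclei rich in intergenic RNA reads the pooled difference turned to 0.0459 points.

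Nuclei differed less in fragment number in pdKO, in a comparison that rested on replicate 2 when all called nuclei were used. The 90th to 10th percentile ratio of fragments was 13.2 and 15.1 in Ctrl and 13.1 and 12.3 in pdKO, with separate ranges and a fold of 0.901 (−0.15 on the log2 scale, exact permutation p = 0.333). The fold was 0.995 in replicate 1 and 0.815 in replicate 2, and without Ctrl replicate 2 the log2 difference was −0.05. The separation was lost among nuclei with at least 1000 UMIs and 1000 fragments (−0.02) and for the 75th to 25th percentile ratio (−0.0026). Without nuclei rich in intergenic reads it was lost too, though the log2 difference grew to −0.22. The log2 ratio was then 3.53 in Ctrl and 3.42 in pdKO of replicate 1, and 3.89 and 3.57 in replicate 2.

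RNA-rich nuclei tended to be fragment-rich in every library. Spearman's rho of UMIs and fragments, across the nuclei of 1 library and so not over independent replicates, was 0.346 and 0.411 in Ctrl and 0.282 and 0.366 in pdKO. The mean was 0.378 ± 0.0460 in Ctrl and 0.324 ± 0.0593 in pdKO (SD, n = 2 each, exact permutation p = 0.667). The difference was −0.0642 in replicate 1 and −0.0453 in replicate 2. With Pearson's r of log10 values the ranges became separate, at a difference of −0.0282. Without intergenic-rich nuclei the difference in rho was −0.0360, with overlapping ranges. Rho was then 0.362 in Ctrl and 0.343 in pdKO of replicate 1, and 0.415 and 0.362 in replicate 2.

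**Figure D3:**
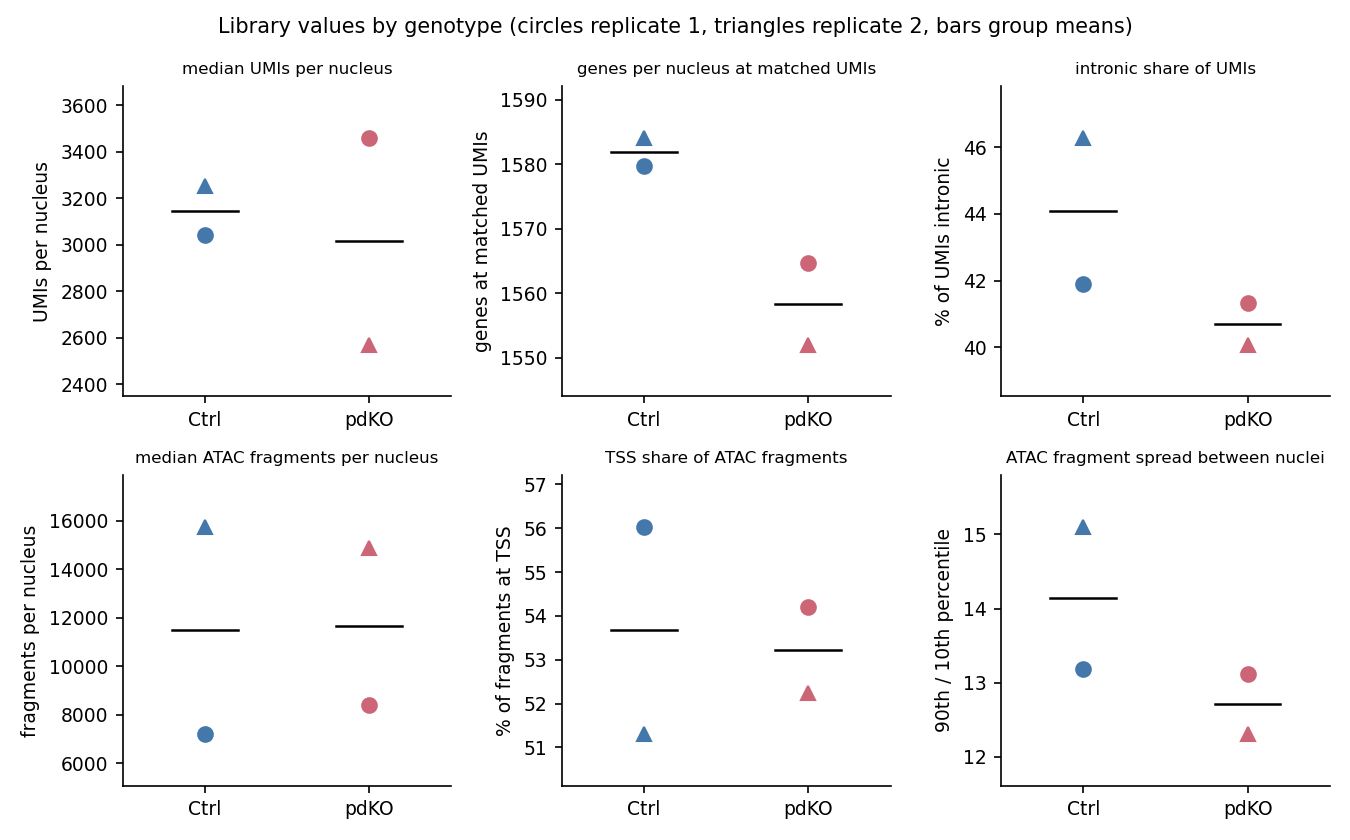
Library values of 6 measures by genotype, with units on each vertical axis (none starts at 0), circles for replicate 1, triangles for replicate 2, and black bars for the means of 2 libraries. The ranges are separate for genes at matched UMIs, the intronic share and the fragment spread, and overlap for UMIs, fragments and the TSS share.

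Chance alone gives separate ranges in 5 of 15 measures on average, whether or not the measures are independent. Of the 15 measures fixed before the data were examined, 3 had separate ranges between the genotypes. These were the genes per nucleus at matched UMIs, the intronic share and the fragment spread, all lower in pdKO. Within both replicates 7 of the 15 measures differed in the same direction, where chance gives 7.5. The p of 0.333 that these 3 measures reached is the smallest that the exact permutation test can give.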

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

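All tests in this part were chosen after the values had been seen. Of 7 measures from table columns that are not among the 15 measures compared, 3 had separate ranges, all higher in pdKO. Chance gives 2.33 on average in either direction, whether or not the measures are independent. Of the 3, the antisense shares of intronic and of exonic reads come from the same RNA reads and are not independent. The intergenic share, another of the 7, was also used above to set nuclei aside in an alternative.

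Of the RNA reads from introns, a larger part ran against the direction of their gene in pdKO. The antisense share of the intronic reads of the median nucleus was 31.1% and 26.2% in Ctrl and 34.5% and 37.4% in pdKO, with means of 28.7% ± 3.47 and 36.0% ± 2.05 (SD, n = 2 each). The difference was 7.33 percentage points (exact permutation p = 0.333, the smallest possible), with 3.43 points in replicate 1 and 11.2 in replicate 2, and without Ctrl replicate 2 it was 4.88. Fewer sense reads raise this share as well as more antisense reads. Of all exonic and intronic reads, sense intronic reads differed by −4.91 points (−2.12 and −7.71 within replicates). Antisense intronic reads differed by 2.87 points (1.26 and 4.47). The pattern is thus partly tied to the lower intronic share above. Of the nuclei, 80.1% in pdKO replicate 1 and 98.2% in pdKO replicate 2 lay above the median of the Ctrl library of the same replicate number. The antisense share of exonic reads was also higher, at 9.13% and 8.62% in Ctrl against 9.59% and 10.2% in pdKO (pdKO mean 9.89%). The share of ATAC reads in chimeric pairs was 0.157% and 0.159% in Ctrl and 0.171% and 0.165% in pdKO (pdKO mean 0.168%).

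For the intronic antisense share, genomic DNA copied along with the RNA would add reads on both strands of introns. Among sense reads alone the intronic share was instead lower in pdKO (−4.35 points, with −1.92 and −6.79 within replicates and separate ranges). Added DNA alone would not lower it, but this largely repeats the lower intronic share of UMIs. A fall in intronic RNA could hide DNA reads, so these values do not decide on DNA. DNA stays open as a source. The intergenic share of the median nucleus was higher in pdKO within both replicates (1.25 and 0.570 points, ranges overlapping), as was the antisense share of exonic reads (0.459 and 1.57 points). In the deposited summaries intergenic reads were 11.2% and 13.2% in Ctrl and 15.6% and 13.4% in pdKO. These ranges were separate only by the narrow gap in replicate 2 (13.24% in Ctrl and 13.44% in pdKO). In replicate 1, intergenic-rich nuclei were 11.9% of Ctrl and 28.7% of pdKO. Their antisense share was below that of the other nuclei (−2.08 points in Ctrl and −2.35 in pdKO). Those other nuclei had a median intergenic share of 6.61% in Ctrl and 7.15% in pdKO. A different mix of RNA-poor and RNA-rich nuclei would shrink the difference at matched UMIs, but over the 8 bins with at least 100 nuclei in each library it was 7.41 points (3.55 and 11.3 within replicates), with pdKO above Ctrl in all 8 bins of both replicates. Over all 14 shared bins it was 6.75 points and only 0.490 in replicate 1, since pdKO lay below Ctrl in 3 bins under 1259 UMIs that held 152 nuclei of that pdKO library. A difference in library preparation cannot be told apart from the genotype. Uncalled barcodes with at most 10 UMIs differed by 7.69 points as well, with 47.8% and 46.2% in Ctrl and 51.9% and 57.4% in pdKO. They may hold free RNA of the same cells, which was not tested. A change in antisense transcription with the genotype or the YFP gate stays open and untested.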

How the results depend on the processing

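Counts, medians and spreads are given here as log2 differences and shares as percentage points, pdKO minus Ctrl. Apart from the replicate block, which is given below, 39 alternatives with all 4 libraries were fixed before the data were examined. Of these 33 kept the direction and the call, and of 17 chosen after seeing the data 13 did. The 75th to 25th percentile ratio gave −0.080 for the UMI spread, with ranges now separate, and −0.0026 for the fragment spread, no longer separate. Without the top 5% of nuclei the UMI spread had separate ranges (−0.094), and no value could be had for the upper tail, which this removes. Nuclei with at least 1000 UMIs and fragments ended the separation of the fragment spread (−0.017). A tail limit of 2 times the median reversed the tail share (−0.176), and Pearson's r separated the ranges of the RNA to fragment correlation (−0.0282). Without intergenic-rich nuclei the nuclei called (−0.029) and the mitochondrial share (0.0459) reversed, and the intronic share (−3.02) and the fragment spread (−0.22) were no longer separate. The reversals of the nuclei called and the mitochondrial share followed from the filter itself. It removed 2280 nuclei of pdKO replicate 1 and 957 of Ctrl replicate 1, and these were nearly free of mitochondrial reads. For the other changes the cause was not tested. At equal reads per nucleus the folds of median UMIs were 1.07 in replicate 1 and 0.823 in replicate 2, against 1.14 and 0.791 before. Their opposite directions thus remained under the saturation model. RNA reads per nucleus differed in the same directions (1.13-fold and 0.931-fold). The model was checked only on reads redrawn from itself, so these values do not exclude depth. The folds of median fragments were 1.07 and 1.05, a turn from 0.946 in replicate 2.

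Libraries of the same replicate number deviated together (r = 0.575 over the 15 measures), but the labels do not say what the number stands for, and 2 pairs do not settle it. The replicate block leaves each difference as it is and asks whether both replicates go the same way (smallest exact sign-flip p 0.5), which 7 measures do, the 3 with separate ranges among them. The other 4 were the UMI spread (−0.078), the tail share (0.471), the RNA to fragment correlation (−0.0548) and linked genes (−0.045).

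Leaving out each library in turn leaves 1 library in an arm, so these values have no test. Of 60 values 17 had the other sign, in 10 of the 15 measures. The ranges were −0.27 to 0.50 for nuclei called, −0.29 to 0.14 for UMIs, −0.22 to 0.085 for genes, −0.49 to 0.64 for fragments, −0.53 to 0.44 for linked genes and −0.093 to 0.058 for peaks. For shares they were −0.0978 to 1.04 for the upper tail, −2.81 to 1.91 for TSS, −3.12 to 2.46 for peaks and −1.75 to 1.38 for mitochondrial reads. Among the 5 measures whose sign held, they were −0.15 to −0.0060 for the UMI spread, −0.0967 to −0.0128 for the correlation, −5.60 to −1.21 for the intronic share, −0.25 to −0.05 for the fragment spread and −0.03 to −0.02 for genes at matched UMIs.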

Other observations

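The tests of explanations in this part were chosen after the patterns had been seen, and nothing here was planned. Each replicate 1 library held a separate set of nuclei with a high share of RNA reads mapped outside annotated genes. In bands of 2 percentage points, the intergenic share had its mode at 6 to 8% in both libraries and a further mode at 26 to 28% in Ctrl (111 nuclei, against 41 in the lowest band between) and at 30 to 32% in pdKO (290 against 106). Nuclei with more than 2 times their library's median share, a limit of 13.6% in Ctrl and 16.1% in pdKO, made up 11.9% of Ctrl replicate 1 (957 nuclei, 95% Wilson interval 11.2 to 12.7%) and 28.7% of pdKO replicate 1 (2280 nuclei, 27.7 to 29.7%). They were nearly free of mitochondrial ATAC reads, with 0.244% and 0.177% against 3.83% and 3.72% in the others. They held more RNA, with median UMIs of 3339 against 3010 in Ctrl and 4013 against 3284 in pdKO, and fewer ATAC fragments, with 0.754 and 0.676 times those of the others. In replicate 2 the median nucleus was already at 13.4% in Ctrl and 14.0% in pdKO, the limit was 26.8% and 28.0%, and the distribution had a single mode. Above that limit lay 3.02% of the Ctrl and 1.43% of the pdKO nuclei, and these held far less RNA than the others (medians of 552 against 3286 UMIs in Ctrl and 587 against 2583 in pdKO). With 1 limit of 20% for all libraries the nuclei above it were 9.05% of Ctrl and 25.7% of pdKO in replicate 1, and 7.83% and 6.56% in replicate 2, where their mitochondrial share was close to that of the others (0.392% against 0.516% in Ctrl and 0.699% against 0.710% in pdKO).

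In replicate 2 the fragments per nucleus had a further mode at about 2 times the most common number, with 227 nuclei against 136 in the lowest band between the modes in Ctrl and 239 against 120 in pdKO. In replicate 1 the counts there (86 against 62 in Ctrl and 98 against 67 in pdKO) did not exceed those of the band below by 3 times the counting error. Nuclei at 1.6 to 2.4 times the mode made up 5.38% and 9.27% in Ctrl and 5.96% and 7.68% in pdKO. The means were 7.32% ± 2.75 and 6.82% ± 1.21 (SD, n = 2 each), with overlapping ranges (exact permutation p = 1).

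Free RNA in the droplets is argued against for the intergenic-rich nuclei of replicate 1, if the uncalled barcodes hold that RNA. A mixture cannot exceed the intergenic share of those barcodes (19.9% and 20.2%), yet 76.0% of the intergenic-rich nuclei in Ctrl and 89.1% in pdKO lay above it. Genomic DNA copied with the RNA would bring antisense intronic reads as well, but their antisense share was below that of the other nuclei (−2.08 percentage points in Ctrl and −2.35 in pdKO). Cytoplasm left on these nuclei would raise exonic over intronic UMIs, and that ratio was 1.16 times the other nuclei's in Ctrl and 1.19 times in pdKO, but it would also bring mitochondria, and the mitochondrial share was at most 0.0637 times that of the others. Uneven lysis, another kind of cell within the sort, or a cell state more frequent in pdKO stay open and were not tested, and the pattern rests on 1 library per genotype.

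For the nuclei at 1.6 to 2.4 times the modal fragment number, random pairs of nuclei as the whole source are argued against only weakly. Their TSS share was below that of simulated pairs summed from the same library in all 4 libraries, with differences from −0.860 percentage points (pdKO replicate 2) to −1.59 (pdKO replicate 1). The gap in TSS share is small, and the pairs were drawn from all called nuclei, these included. The intronic share of UMIs was below that of the pairs too, with differences of −2.92 points in Ctrl and −3.97 in pdKO of replicate 1. In replicate 2 these were −0.336 and −0.948 points. Median UMIs of the nuclei at 1.6 to 2.4 times the mode were 0.945 (Ctrl replicate 2) to 0.996 (pdKO replicate 2) times those of the pairs. Replicated DNA could contribute, but their UMIs, at 2.13 to 2.20 times those at the mode, are what pairs of nuclei would give as well, so that cycling cells and a share of pairs cannot be told apart here.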
